A study of Homo sapiens with 6 samples.

How the data were processed

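RNA from 3 human hepatoma cell lines was hybridised to 6 single-colour Agilent arrays labelled with Cy3. HepG2 came from a hepatoblastoma, and Hep3B and Huh7 came from hepatocellular carcinomas, per the labels. Each line had 1 array of cells kept for 48 h with 0.1 mmol/L dimethyl dicarboxylate biphenyl (DDB, a synthetic compound used as a liver drug) and 1 array of control cells kept with 7.6 g/L dimethyl sulfoxide (DMSO). The labels do not say whether the DDB cultures held DMSO as well.

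The scanner values are spot intensity values made by the authors with Agilent Feature Extraction 11.0.1.1, per the file headers, and background subtraction and detrending of each array are recorded there. The headers show no scaling between arrays. All 6 arrays lay on 1 slide and were scanned in 1 run. HepG2 was in slide row 1 and the other 2 lines were in slide row 2, and within each line the control array lay in the column before the DDB array. Slide row therefore goes with cell line, and column order goes with treatment. The deposited value table holds log2 intensity values for 22737 probes. Each of its columns had a median of 8.81, and sorted columns differed by at most 0.00049, so the table had been quantile normalized, and within an array its values tracked log2 processed intensity (Pearson r of 0.99996 to 0.99999 across probes, which are not independent replicates). Of its probes, 22729 were well above background on all 6 arrays. Its scale and direction were settled by this comparison, and the filter behind it is not given in the sources used here. It served as an alternative source of values.

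Processed intensities were converted to log2, spots of a probe were averaged, and the 75th percentile of each array was subtracted. Of 58201 non-control probes, 31 were left out because every spot on an array carried an outlier mark. RefSeq accessions, compared without versions with a table of assembly GRCh38.p14, named 31091 probes and 22432 gene symbols, and 27079 probes stayed unnamed. The file headers name build hg19 for the probe annotation, so no coordinates are given, and the table was used for names and for the order of genes along chromosomes. Probes well above background on at least 2 of the 6 arrays were kept. Each gene was represented by its brightest probe, and 4378 symbols had more than 1 probe past the filter. This left 24784 genes and unnamed transcripts for testing, 16147 of them with a symbol, and 18374 were well above background on all 6 arrays. Some members of the gene lists had no named probe and were not analysed here, among them POR, GSTA1, UGT1A1, PLK1, DDX58 and LYZ.

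Each line and treatment had 1 array, so the 3 lines served as 3 pairs for the effect of DDB. The pairing comes from the cell line. limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table) fitted cell line and treatment to all 6 arrays, with 2 residual degrees of freedom, a prior of 1.96 degrees of freedom and a prior SD of 0.132 on the log2 scale. P-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Contrasts between lines used both arrays of each line and also required an absolute log2 difference of at least 1, a 2-fold difference. Nothing in the labels says that the arrays of a line came from separate cultures, so p-values measure only the spread between these arrays. DDB against control within a line, and the control arrays of 2 lines, were compared as values without a test. Where a gene was not well above background in the dimmer group, the fold is a lower bound. The bright group's mean was then set against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal.

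The gene rule, the tests, the gene lists and most alternatives were fixed before the data were examined. For DDB across lines, the rule named the 10 genes of each direction with the largest smallest difference over the 3 lines, among genes well above background on all 6 arrays, because fewer than 5 genes of either direction passed the test. For each line it named the 8 highest and 8 lowest differences among genes well above background on both arrays. Between lines it named, for each line, the 8 genes highest and the 5 lowest against both others. GPT and GOT1 were fixed by name, and up to 4 members of each of 26 gene lists were taken by size of mean difference. Unnamed and uncharacterised transcripts, XIST and Y-linked genes were left out. Some genes and 1 list that the rule named are not reported here. Members of lists that were not well above background on all 6 arrays are not named for DDB, a choice made after the values were seen. The lists covered hepatocyte functions, drug metabolism, stress responses, the cell cycle, lipid metabolism, inflammation, tumour-related genes and markers of other cell types. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Within a line, a list's median was placed among 10000 random lists of the same size matched on mean signal.

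The DDB test was tested on simulated data for 24784 genes in 3 pairs. It recovered 3 of 100 genes changed 2-fold and 78 of 100 genes changed 4-fold, with 6 false calls, and made 0 calls where no gene was changed. Between 45.8% and 49.5% of probes were well above background on each array, and 0 were saturated. Spots well above background of probes repeated 10 times had an SD of 0.057 on the log2 scale about their probe's median. The number of arrays limits the precision. Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling by the median, no filter, a filter for all 6 arrays, the mean of a gene's probes, the authors' value table, other variance priors, other thresholds, no cell line term, and leaving out each line or array. Normexp had been set for mean spot signals and was run on the median spot signals that the scanner values hold, a choice made after the data had been seen. So were the count of genes well above background on both arrays, and several added settings for the lists and the similarity of responses.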

Results

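Messenger RNA and non-coding RNA were measured on 6 one-colour arrays, with 1 array of control cells and 1 array of DDB-treated cells for each of HepG2, Hep3B and Huh7. There were no replicate arrays within a line and treatment. Between 26648 and 28782 probes were well above background on each array, 0 were saturated, and the 75th percentile of processed signal lay between 200 and 254 units per array. The median coefficient of variation of processed signal over repeated spots of a probe was at most 3.72% on each array. Differences are given on the log2 scale, and 1 unit is a 2-fold difference.

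The first comparison asked what DDB altered in all 3 lines. CYP1A1, an enzyme that oxidises polycyclic aromatic compounds and a classic target of the aryl hydrocarbon receptor, had the largest mean among the genes named as higher with DDB, at 1.09 (SD 0.19, n = 3 lines), with 1.31 in HepG2, 1.01 in Hep3B and 0.96 in Huh7. CYP26A1, which breaks down retinoic acid, was higher by a mean of 0.79 (SD 0.20), LOXL2, which cross-links collagen, by 0.73 (SD 0.20), and FOS, a subunit of the AP-1 transcription factor, by 0.68 (SD 0.21). The metal-binding metallothioneins MT1E, MT1B and MT1X were higher by means of 0.88 (SD 0.43), 0.80 (SD 0.41) and 0.50 (SD 0.11). Among genes lower with DDB were ASAP1-IT1, a non-coding RNA, at -1.03 (SD 0.41), PIGM, a mannosyltransferase of the membrane anchor GPI, at -0.82 (SD 0.55), and PDCD1, an inhibitory receptor of lymphocytes, at -0.81 (SD 0.76). Huh7 weighed most in the means of PIGM and PDCD1, at -1.46 and -1.69. PIGM was at -0.47 and -0.54, and PDCD1 at -0.35 and -0.40, in HepG2 and Hep3B.

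None of these differences passed the test. limma called 0 of 24784 genes at an adjusted p of 0.05, the smallest adjusted p was 0.844, and 1283 genes were at an unadjusted p of 0.05, where 1239.2 would be so with no effect. Of the 1283, 587 were higher and 696 were lower. CYP1A1 passed only with normexp background correction, with a mean of 0.99 and an adjusted p of 0.0393, and its adjusted p ranged from 0.0393 to 1.00 over the alternatives tried. In the test on simulated data this design recovered 3 of 100 genes changed 2-fold, so a 2-fold effect would mostly be missed. Across genes, 7327 of the 24784 (29.6%) differed in the same direction in all 3 lines, where 25% would by chance if lines and genes were independent.

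The other genes named by the rule as higher were DEFB108B, a beta-defensin, with a mean of 0.76 (SD 0.20), FSCN2, an actin-bundling protein, with 0.54 (SD 0.09), and HBM, a globin, with 0.47 (SD 0.02). Lower ones included 3 bitter taste receptor genes, TAS2R30 with a mean of -0.88 (SD 0.40), TAS2R14 with -0.66 (SD 0.31) and TAS2R31 with -0.55 (SD 0.19). The taste receptors and the metallothioneins have near-identical relatives, so the signal of a probe cannot be assigned to 1 member alone. N4BP2L2-IT2, a non-coding RNA, had a mean of -0.55 (SD 0.16), SNORA23, a small nucleolar RNA, -0.48 (SD 0.09), SPON2, a matrix protein, -0.47 (SD 0.11), and ZG16, a secreted lectin, -0.43 (SD 0.09). Each of the 20 genes had an adjusted p of 0.844. With normexp the means of 11 of the 20 were over 1.5 times smaller, among them CYP26A1 at 0.45, DEFB108B at 0.27, ASAP1-IT1 at -0.53, PIGM at -0.21 and PDCD1 at -0.42.

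**Figure D1:**
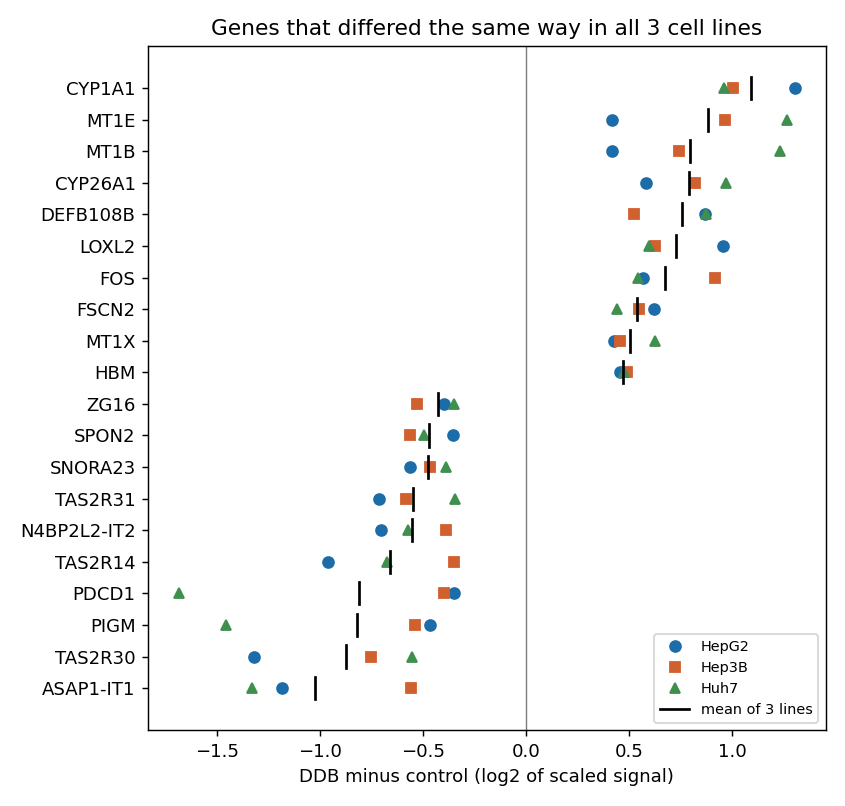
The horizontal axis is the difference in log2 scaled signal between DDB and control, and each marker is 1 pair of arrays in HepG2 (circles), Hep3B (squares) or Huh7 (triangles), with a black bar for the mean of the 3 lines. CYP1A1 lay between 0.96 and 1.31 in the 3 lines, and none of the 20 genes passed the test.

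The metallothionein family, which was chosen after its values were seen, was higher with DDB in each line. All members well above background on both arrays of a line were higher, 10 in HepG2, 8 in Hep3B and 9 in Huh7, under each of the 4 scalings tried. Their medians were 0.38, 0.79 and 1.27 in the scaling used, and the HepG2 median was 0.245 with quantile normalization. At least 2-fold higher, bounds counted, were 0 members in HepG2, 1 in Hep3B and 6 in Huh7. MT2A was higher by 0.11, 0.84 and 1.31 in HepG2, Hep3B and Huh7, and MT1G by 0.39, 2.40 and 1.66. MT1A was the lowest in Hep3B, at 0.09. No member passed the test across lines, and the difference between lines was not tested.

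**Figure D2:**
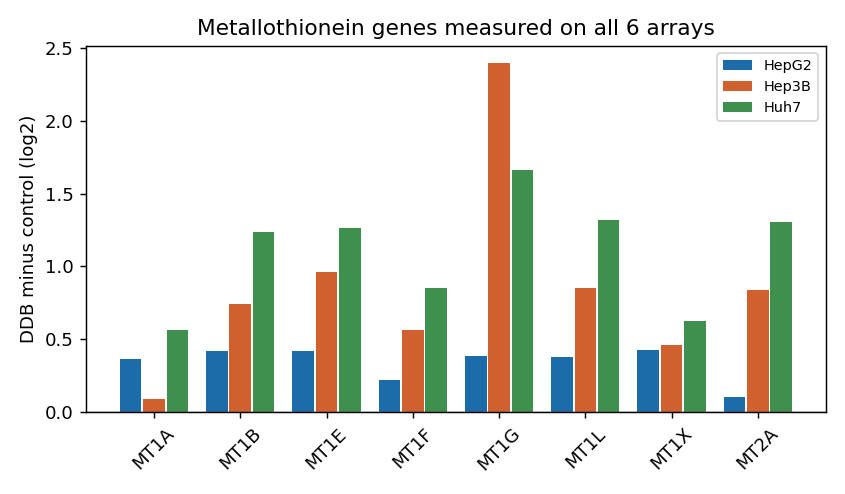
The vertical axis is the difference in log2 scaled signal between DDB and control, and each bar is 1 pair of arrays in HepG2, Hep3B or Huh7 for the 8 metallothionein genes well above background on all 6 arrays. All bars are above 0, and MT1G in Hep3B is the highest at 2.40.

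GPT, which encodes alanine aminotransferase, had a mean of 0.003 (adjusted p = 0.993). GOT1, which encodes cytosolic aspartate aminotransferase, had a mean of 0.09 (adjusted p = 0.863), with 0.25 in HepG2. A change in either transcript was not detectable with these arrays.

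Of the 26 gene lists, the targets of NRF2, a transcription factor of the antioxidant response, were the one list past the threshold for DDB. Of its 21 measured members 11 were higher in all 3 lines and 0 were lower in all 3, with a median of 0.105 and an adjusted p of 0.0390 in limma's camera. The call was lost with an estimated correlation (adjusted p = 0.861 with an estimated correlation) and with fry (adjusted p = 0.803), and it was also lost in 7 other settings, among them without HepG2 (0.288). Among its members were SRXN1, which repairs oxidised peroxiredoxins, at 0.24, TXN, a thioredoxin, at 0.23, and GCLC, of glutathione synthesis, at 0.22. No member passed the test on its own, and 2 members were at an unadjusted p of 0.05.

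Among drug-metabolising genes, 2 of 13 cytochrome P450 genes were higher in all 3 lines and 2 were lower in all 3 (median -0.0156, adjusted p = 0.826). The mean over these 13 genes, 0.0889, had the opposite sign from the median and from camera. CYP1A2, which oxidises caffeine and other drugs, was higher by a mean of 0.29. Of 7 targets of the aryl hydrocarbon receptor 2 were higher in all 3 lines and 0 lower (median 0.0668, adjusted p = 0.210), with TIPARP, a feedback inhibitor of that receptor, at 0.24. CYP1A1 passed when adjusted over the list alone, both among the P450 genes and among the targets of this receptor. Of 9 targets of the xenobiotic receptors PXR and CAR, 2 were higher and 2 lower in all 3 lines (median -0.0156, adjusted p = 0.557), with SULT2A1, a sulfotransferase, at -0.32 and ABCC2, a canalicular export pump, at 0.24. Of 19 conjugation enzymes 7 were higher in all 3 lines and 1 was lower (median 0.0593, adjusted p = 0.557), with SULT1C2, a sulfotransferase, at 0.35 and MGST1, a microsomal glutathione transferase, at 0.19.

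Among hepatocyte functions, 3 of 20 secreted hepatocyte proteins were higher and 3 lower in all 3 lines (median -0.0106, adjusted p = 0.325), with TTR, a carrier of thyroid hormone, at -0.25 and TF, the iron carrier transferrin, at -0.17. Of 15 hepatocyte transcription factors 4 were higher and 0 lower in all 3 lines (median 0.0693, adjusted p = 0.596), with ONECUT1 at -0.22 and FOXA3 at 0.15. Of 15 aminotransferases 3 were higher and 1 lower in all 3 lines (median 0.0734, adjusted p = 0.851), with BCAT1, of branched-chain amino acids, at 0.16 and AGXT at -0.15. Of 15 genes of bile acid synthesis and transport 2 were higher and 1 lower in all 3 lines (median 0.0741, adjusted p = 0.565). Of 12 acute phase proteins 2 were higher and 1 lower in all 3 lines (median -0.0895, adjusted p = 0.519), with HP, haptoglobin, at -0.39.

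For lipid metabolism, 1 of 20 cholesterol genes was higher and 2 were lower in all 3 lines (median -0.0273, adjusted p = 0.386), with MSMO1, of sterol synthesis, at 0.19. Of 14 fatty acid synthesis genes 2 were higher and 5 lower in all 3 lines (median -0.0245, adjusted p = 0.386), with GPAM at -0.19 and ACACA at -0.16. Of 17 genes of fatty acid oxidation and PPAR alpha 2 were higher and 6 lower in all 3 lines (median -0.0277, adjusted p = 0.236).

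For stress responses, 2 of 20 genes of the unfolded protein and integrated stress response were higher and 0 lower in all 3 lines (median 0.0529, adjusted p = 0.302), with ASNS, asparagine synthetase, at 0.39. Of 12 heat shock genes 4 were higher and 0 lower in all 3 lines (median 0.100, adjusted p = 0.237), with the chaperone HSPA8 at 0.17. Of 16 hypoxia and glycolysis genes 3 were higher and 1 lower in all 3 lines (median 0.0782, adjusted p = 0.386).

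For the cell cycle, 1 of 20 mitosis genes was higher and 1 lower in all 3 lines (median 0.0343, adjusted p = 0.826), with BUB1B, a spindle checkpoint kinase, at 0.18. Of 20 DNA replication genes 2 were higher and 0 lower in all 3 lines (median 0.0785, adjusted p = 0.302), with RRM2 at 0.17. Of 13 NF-kB inflammatory genes 0 were higher and 1 lower in all 3 lines (median -0.0474, adjusted p = 0.325), with CXCL5, a chemokine, at -0.15. Of 16 interferon-stimulated genes 0 were higher and 2 lower in all 3 lines (median -0.00225, adjusted p = 0.519), with IFI6 at -0.31.

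Among tumour-related genes, 7 of 16 mesenchymal and matrix genes were higher and 1 lower in all 3 lines (median 0.127, adjusted p = 0.325), with CCN1, a matrix-associated signalling protein, at 0.37. Of 15 oncofetal and progenitor genes 2 were higher and 3 lower in all 3 lines (median -0.0383, adjusted p = 0.441), with AFP, alpha-fetoprotein, at -0.16. Of 14 targets of Wnt and beta-catenin 5 were higher and 2 lower in all 3 lines (median 0.0527, adjusted p = 0.557), with DKK1, a secreted inhibitor of Wnt, at 0.42. Of 10 cancer-testis antigens 4 were higher and 1 lower in all 3 lines (median 0.125, adjusted p = 0.302). Of 10 markers of non-parenchymal and blood cells 1 was higher and 2 were lower in all 3 lines, with CD14, a monocyte receptor, at -0.41. Their median was 0.0701 (adjusted p = 0.826), and camera gave the opposite direction for this list. The counts and medians of lists take in members that were near background on some arrays. With an estimated correlation the adjusted p of the 26 lists ranged from 0.861 to 0.989.

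Within HepG2, EMP1, an epithelial membrane protein, was higher with DDB by 2.43, and NCCRP1 by 1.97. ITIH6 was higher by 2.02, and FA2H, which hydroxylates fatty acids, and SPOCD1 were each 2.99-fold higher. TIRAP, an adaptor of Toll-like receptors, was higher by 2.42, and ZNF197 by 1.71, but a second TIRAP probe gave 0.18 and a second ZNF197 probe gave 0.12. The largest negative differences were those of CHST5, a sulfotransferase, at -1.87, XAGE3, a cancer-testis antigen, at -1.53, TAS2R30 at -1.32 and PLA2G4F, a phospholipase, at -1.31. Non-coding transcripts followed, FAR2P1 at -1.26, VPS33B-DT at -1.24, SNORD109B at -1.23 and MFF-DT at -1.20.

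In HepG2, 138 genes were at least 2-fold higher and 200 at least 2-fold lower with DDB, of which 66 and 57 were lower bounds because the other array was not well above background. Quantile normalization gave 150 higher and 140 lower, and the median difference over all genes tested was 0.0778 in the scaling used, 0.108 with median scaling and 0.0117 with quantile normalization. Of 21081 genes well above background on both arrays, 94.0% were within 1.5-fold (SD 0.31). With normexp 13 of the 16 genes the rule took in HepG2 were less than 2-fold apart. With 1 array on each side no test of these differences was made, in this line or in the others.

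Within Hep3B, the genes highest with DDB were OR2M5, an olfactory receptor gene, at 2.49, the metallothionein MT1G at 2.40, ALOX12B, a lipoxygenase of the skin barrier, at 2.23, and KRTAP4-2, a hair keratin-associated protein gene, at 2.17. ACTL8 was higher by 2.08, though a second ACTL8 probe gave 0.30, and MYCBPAP was higher by 2.04. CHST9, a sulfotransferase, was higher by 1.60, and FHAD1 by 1.54. The lowest were ARHGAP29, which inactivates small GTPases, at -2.06, XKR7 at -1.96, CPEB2, a regulator of translation, at -1.64, PLXNB3, a semaphorin receptor, at -1.58, and TBX1, a T-box transcription factor, at -1.58. MON2 was at -1.55, with 0.21 for its second probe, NLRP7 at -1.50 and A4GNT, a glycosyltransferase, at -1.43. At least 2-fold differences numbered 162 higher and 156 lower, of which 98 and 99 were lower bounds, and 97.4% of 20648 genes well above background on both arrays were within 1.5-fold (SD 0.24). With normexp 8 of the 16 genes the rule took in Hep3B were less than 2-fold apart.

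Within Huh7, IFNE, a type I interferon, was higher with DDB by 3.23, and BHLHA15, a transcription factor of secretory cells, by 2.14. ADAMTSL2, a matrix glycoprotein, was higher by 2.03, and SLC7A6, an amino acid transporter, by 1.74. Other ADAMTSL2 probes gave -0.649 and 1.098 in Huh7, each well above background on only 2 of the 6 arrays. HBD, a globin, was higher by 1.75, and the non-coding EIF2AK3-AS1, CAND1.11 and SNORD67 by 2.15, 1.89 and 1.85. HLA-DMA, which helps load peptides onto MHC class II, was at -3.83, but its second probe gave 0.27. PTGES2-DT was at -2.43, ZNF799 at -2.23, PLEKHG4B at -2.09, TLE1-DT at -2.06, S100A16, a calcium-binding protein, at -1.90, TAS2R43 at -1.86 and PRICKLE2, of planar cell polarity, at -1.74. At least 2-fold differences numbered 152 higher and 177 lower, of which 64 and 108 were lower bounds, though 88 were higher and 69 lower among the 21845 genes well above background on both arrays. Of the 21845, 96.5% were within 1.5-fold (SD 0.27). With normexp 11 of the 16 genes the rule took in Huh7 were less than 2-fold apart.

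The responses of the 3 lines were also set against each other. CCL3, an inflammatory chemokine chosen after its values were seen, was the only gene at least 2-fold higher in all 3 lines (1.87 in HepG2, 1.07 in Hep3B and 1.01 in Huh7, some of them bounds), and 0 genes were at least 2-fold lower in all 3. Genes at least 2-fold higher in both lines of a pair numbered 5 for HepG2 and Hep3B, 8 for HepG2 and Huh7, and 11 for Hep3B and Huh7, against 0.375, 0.640 and 0.761 for independent lists drawn from genes well above background on at least 1 array of each line of the pair. Those lower in both numbered 1, 5 and 19, against 0.630, 0.789 and 0.926, and those opposite in direction numbered 5, 9 and 32, against 1.05, 1.45 and 1.71. Across 24784 genes, which are not independent replicates, Pearson's r of the differences was 0.0242 for HepG2 and Hep3B, 0.0382 for HepG2 and Huh7 and 0.0436 for Hep3B and Huh7. Over the 18374 genes well above background on all 6 arrays r was 0.0848, 0.0563 and 0.150, and Spearman's correlation was 0.0868, -0.0228 and 0.177. For HepG2 and Huh7, r was -0.0259 with normexp.

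The control comparisons named in the study's design asked how the 3 lines differ from each other, and here both arrays of each line were used for the test. HepG2 had much more FAM3B, a secreted cytokine-like protein, than Hep3B (at least 584-fold) and Huh7 (at least 707-fold). It also had more ACSS1, a mitochondrial acetyl-CoA synthetase (at least 244-fold and 296-fold), HSPA12A, a heat shock protein relative (209-fold and 253-fold), the non-coding BOK-AS1 (188-fold and 227-fold) and SLCO4A1, an organic anion transporter (126-fold and 153-fold). SLC13A3, a dicarboxylate transporter, was higher by 9.20 than in Hep3B (SE 0.17), and HEPACAM, a cell adhesion protein, was at least 287-fold higher than in Huh7. JAK3, a cytokine receptor kinase, was also named as higher, but another JAK3 probe was well above background in both other lines, and with the filter for all 6 arrays its differences were 0.20 and 0.39 and did not pass. HepG2 had far less UCHL1, a ubiquitin hydrolase (at least 4035-fold and 10215-fold lower than Hep3B and Huh7), VIM, vimentin (2364-fold and 747-fold), GC, the vitamin D-binding protein (4310-fold and 589-fold), CXCL1 (1594-fold and 724-fold) and LDOC1 (604-fold and 499-fold).

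Hep3B stood out for the cancer-testis antigens MAGEA2B (at least 1964-fold and 2088-fold higher than HepG2 and Huh7) and MAGEA12 (583-fold and 620-fold). It also had more MSN, moesin, which links actin to the membrane (at least 191-fold and 203-fold), SLFN11, a factor that blocks stressed replication forks (141-fold and 149-fold), CDH6, a cadherin (82.5-fold and 87.7-fold), DUSP23, a phosphatase (157-fold and 167-fold), ERICH5 (224-fold and 238-fold) and ZNF239 (103-fold and 110-fold). It had less SAT2 (at least 2229-fold and 2004-fold), RPS6KA3, a kinase of the MAPK pathway (921-fold and 1332-fold), SULF2, which edits heparan sulfate (337-fold and 194-fold), MX2, an antiviral GTPase (159-fold and 193-fold) and ARSL, a sulfatase (98.6-fold and 96.6-fold). MAGEA2B has near-identical relatives, so its signal cannot be assigned to it alone.

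Huh7 had more GSTP1, a glutathione transferase, by 13.39 over HepG2 (SE 0.09) and by 13.70 over Hep3B. It also had more MARVELD1 (at least 1004-fold and 881-fold), TCF4, a helix-loop-helix transcription factor (240-fold and 211-fold), CA4, a carbonic anhydrase (219-fold and 192-fold), DCAF4L2 (172-fold and 151-fold) and the non-coding HOXD-AS2 (179-fold and 157-fold). SLPI, a protease inhibitor, was at least 397-fold higher than in HepG2, and HOXB9, a homeobox factor, at least 471-fold, and both were near background in Hep3B on at least 1 array. KRT19, a keratin of bile duct cells, was lower in Huh7, at -10.04 against HepG2 and -10.29 against Hep3B. MAGED1 (at least 580-fold and 346-fold lower than HepG2 and Hep3B), MAGED4B (391-fold and 275-fold), GSTT1, another glutathione transferase (487-fold and 243-fold), and MGMT, which repairs alkylated guanine (260-fold and 252-fold), were lower too.

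Adjusted p-values of the genes named between lines ranged from 5.88e-05 to 0.00151, with standard errors between 0.09 and 0.65. limma called 3651 genes higher and 3711 lower in HepG2 than in Hep3B (29.7% of genes), 3999 higher and 4296 lower in HepG2 than in Huh7 (33.5%), and 3209 higher and 3532 lower in Hep3B than in Huh7 (27.2%). Genes higher than in both other lines numbered 2203 in HepG2, 1443 in Hep3B and 2072 in Huh7, and genes lower than in both numbered 2000, 1249 and 1522. The 2 arrays of a line also differ in treatment, and the spread between separate cultures of a line is unknown.

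GPT was lower in Huh7 than in HepG2 by 2.41 (adjusted p = 0.000255) and than in Hep3B by 3.29 (adjusted p = 0.000204), and HepG2 minus Hep3B was -0.89 (adjusted p = 0.00363), under the 2-fold minimum. GOT1 did not pass in any pair, at 0.01 (adjusted p = 0.958) for HepG2 minus Hep3B, 0.33 (0.0745) for HepG2 minus Huh7 and 0.33 (0.0866) for Hep3B minus Huh7.

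Interferon-stimulated genes were higher in HepG2. Of 16 members 9 rose and 1 fell against Hep3B (median 1.75, adjusted p = 0.00284), and 12 rose and 0 fell against Huh7 (median 2.06, adjusted p = 0.00110), each with adjusted p = 0.895 with an estimated correlation. BST2, which tethers viruses to the cell surface, was 128-fold higher than in Hep3B and at least 565-fold higher than in Huh7, and MX1, an antiviral GTPase, was 6.91-fold and 3.01-fold higher. Of 14 Wnt and beta-catenin targets 10 rose and 2 fell in HepG2 against Hep3B (median 3.13, adjusted p = 0.0247), and 11 rose and 2 fell against Huh7 (median 3.52, adjusted p = 0.00677), each with adjusted p = 0.895 with an estimated correlation. The feedback inhibitors NKD1 (6.83 against Hep3B, SE 0.25) and AXIN2 (3.78 and 4.52) were higher in HepG2, while DKK1 (-5.67 and -1.26) was lower. Of 16 hypoxia and glycolysis genes 9 rose and 2 fell in HepG2 against Hep3B (median 1.03, adjusted p = 0.0247), and 8 rose and 2 fell against Huh7 (median 0.902, adjusted p = 0.0247), each with adjusted p = 0.895 with an estimated correlation. SLC2A1, a glucose transporter, was higher by 5.68 and 4.21.

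Secreted hepatocyte proteins were higher in HepG2, where 5 of 20 rose and 0 fell against Hep3B (median 0.847, adjusted p = 0.0463), and 11 rose and 2 fell against Huh7 (median 1.09, adjusted p = 0.00781), each with adjusted p = 0.895 with an estimated correlation. SERPINC1, antithrombin, was higher by 128-fold and 14.6-fold, and APOH, a plasma lipoprotein component, by 1.24 and 4.93. Of 12 acute phase proteins 9 rose and 2 fell in HepG2 against Huh7 (median 2.66, adjusted p = 0.0290, and adjusted p = 0.895 with an estimated correlation). HAMP, the iron hormone hepcidin, was higher by 8.11, ORM2 by 4.92 and HP by 3.55. AFP, of the oncofetal and progenitor list, was higher by 4.88 in HepG2 than in Hep3B. Of the 15 genes of that list 3 rose and 6 fell in this pair (median -0.358, adjusted p = 0.630 in camera). Of 13 NF-kB inflammatory genes 0 rose and 10 fell in HepG2 against Hep3B (median -4.37, adjusted p = 0.000196), and 10 rose and 0 fell in Hep3B against Huh7 (median 1.40, adjusted p = 0.00102), each with adjusted p = 0.895 with an estimated correlation. CXCL8, a chemokine for neutrophils, was at 3.28 in Hep3B against Huh7, and BIRC3, an inhibitor of apoptosis, was at -5.09 in HepG2 against Hep3B and 3.81 in Hep3B against Huh7.

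Of 21 NRF2 targets 8 rose and 1 fell in HepG2 against Hep3B (median 0.541, adjusted p = 0.00677), and 0 rose and 12 fell in Hep3B against Huh7 (median -1.09, adjusted p = 0.00125), each with adjusted p = 0.895 with an estimated correlation. AKR1B10, an aldehyde reductase, was at 8.11 and -9.43 in these pairs, and NQO1, a quinone reductase, at 2.18 and -3.94. In Hep3B against Huh7, 0 of 20 cholesterol genes rose and 9 fell (median -0.614, adjusted p = 0.00311), and 0 of 14 fatty acid synthesis genes rose and 6 fell (median -0.642, adjusted p = 0.0290), each with adjusted p = 0.895 with an estimated correlation. INSIG1, which holds back sterol synthesis, was at -2.57, DHCR7 at -2.48, and FADS2, a fatty acid desaturase, at -4.89, while HMGCS1 was 4.01-fold lower.

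Among cell cycle genes, 0 of 20 mitosis genes rose and 6 fell in HepG2 against Hep3B (median -0.860, adjusted p = 0.00960), among them BUB1B at -1.69 and AURKB at -1.52. Of 20 DNA replication genes 0 rose and 5 fell in HepG2 against Huh7 (median -0.658, adjusted p = 0.0403), among them MCM6, of the replicative helicase, at -1.35 and RRM2 at -1.22. Both of these list calls were lost, with adjusted p = 0.936 with an estimated correlation. Of 10 cancer-testis antigens 1 rose and 6 fell in HepG2 against Hep3B (median -4.09, adjusted p = 0.0305, and adjusted p = 0.895 with an estimated correlation), among them MAGEA1, at least 47.3-fold lower. Of the 78 list tests between lines 20 passed with the preset correlation, 2 of them for a list that is not reported here, and 0 passed with an estimated correlation.

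On the control arrays alone, as the study's design names the comparison, 3418 genes were at least 2-fold higher and 3698 lower in HepG2 than in Hep3B, of which 988 and 1184 were bounds. HepG2 against Huh7 gave 3981 higher and 4216 lower (1083 and 1610 bounds), and Hep3B against Huh7 gave 3238 higher and 3255 lower (818 and 1125 bounds). For GPT the control arrays gave 2.43 between HepG2 and Huh7, and 3.33 between Hep3B and Huh7. Of the genes called from both arrays of each line, 94.6%, 94.4% and 95.2% were also at least 2-fold apart in the same direction on the control arrays. Those control arrays are part of the data behind the calls, so these shares are not an independent check.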

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

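The test of the other targets of the aryl hydrocarbon receptor and the test of the range of metallothionein differences were chosen only after the results were seen. The differences of at least 2-fold within a line came mostly from dim genes. Of 985 such differences over the 3 lines, 43 (4.37%) lay above the median signal of the genes tested, and 492 were bounds against an array not well above background, so signal near background is consistent with most of them. Of 28 with a second probe well above background on both arrays, 7 (25%) had a second probe that differed the same way by at least 50% of the size, which leaves faults of single spots open as a part of the cause. Among repeated spots well above background such faults were rare. At least 2-fold from their probe's median were 0 of 16616, and 1 of 17080 with outlier-marked spots kept. Spots of probes not well above background were not covered by these counts. A response to DDB in each line stays open and was not tested, since column order on the slide, and possibly DMSO, goes with treatment.

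CYP1A1 was higher with DDB in all 3 lines, at 1.31, 1.01 and 0.96. Among transcripts well above background on all 6 arrays, 3 with the real labels, CYP1A1 and 2 unnamed ones that were lower, differed at least as much in 1 direction in all 3 lines, against at most 1 when control and DDB were swapped within a line, and counts as small as these leave chance among the genes tested open. If DDB activated the aryl hydrocarbon receptor, other targets might be higher too. The median of the other 6 targets was 0.0591, at percentile 77.2 of matched random lists, so as a set they did not stand out from random lists. Each of the 6 had a positive mean, but only TIPARP was higher in all 3 lines. In HepG2 all 6 were higher, from 0.13 for CYP1B1 to 0.80 for UGT1A6, while directions were mixed in Hep3B and Huh7. The whole list, CYP1A1 included, had a median of 0.42 in HepG2, at percentile 99.97 of matched random lists. It lay at percentile 51.1 in Hep3B and 26.15 in Huh7. Other lists also lay high in HepG2, among them mitosis at 99.45. With 1 pair of arrays per line and lines that differ, this test is unable to decide on activation of the receptor. Activation of the receptor, a difference tied to column order and a difference in DMSO, if the DDB cultures held none, cannot be told apart here. Replicate cultures with the same DMSO in both treatments would be needed.

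The metallothioneins were higher with DDB, on the log2 scale most in Hep3B and Huh7. The lines started from unequal levels, and control signals were highest in HepG2. MT1E, for example, was at 8.13 in HepG2 control cells, 0.46 in Hep3B and 3.09 in Huh7, so the log2 differences do not rank the absolute rise. The range over the family in Hep3B was 2.30, from MT1A at 0.09 upward for genes well above background. This range cannot decide on cross-hybridisation of 1 transcript to all probes. Signal added to probes that start at unequal levels would give unequal log2 differences. In Hep3B control cells MT1A was at 4.42 and MT1G at -2.44. A response to metal stays open. SLC30A1, a zinc exporter that zinc induces, was higher by 0.28 in Hep3B and by 0.11 in Huh7. The sizes set in advance for and against a metal response were each required in both lines, and neither was met. Neither line reached the size set for it. SLC30A1 was higher by 0.31 in HepG2, where the metallothioneins were higher by the least. Another effect of DDB on these genes, or a difference in DMSO between the cultures, could give the same values and was not tested.

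Of the 10 splits of the 6 arrays into 3 and 3, too few exist for a share under 0.05. The real split called 0 genes in limma and the highest other split called 11, and with a real count of 0 all 10 of the 10 splits had to give a count as large, so this count tells nothing. At an unadjusted p of 0.05 the real split gave 1283, the highest other 3065, and 3 of the 10 gave as many. The other 3 splits that part all 3 pairs, as the real one does, gave 757, 770 and 989. The other 6 rest on the difference within 1 line, and gave 3065 on the HepG2 pair, 1174 on the Hep3B pair, where the 11 calls were, and 1225 on the Huh7 pair.

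In the results below, effects went in opposite directions in pairs of lines, and the differences were not tested. For the unfolded protein and integrated stress response the list medians with DDB were 0.21 in HepG2, -0.03 in Hep3B and 0.07 in Huh7, so HepG2 and Hep3B differed by 0.243 and Huh7 and Hep3B by 0.101. For mitosis the list medians were 0.25 in HepG2, -0.04 in Hep3B and -0.11 in Huh7, so HepG2 differed from Hep3B by 0.281 and from Huh7 by 0.356. With quantile normalization the HepG2 medians were 0.115 for the stress response list and 0.112 for mitosis. FHAD1 was higher in Hep3B and lower in Huh7, and the difference between the lines was 3.78 with a bound used for Huh7. KRTAP4-2 was lower in HepG2 and higher in Hep3B, a difference of -3.68 with a bound used for HepG2. TAS2R43 was lower in HepG2 and Huh7 and higher in Hep3B, with HepG2 minus Hep3B at -2.16 and Hep3B minus Huh7 at 2.87.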

How the results depend on the processing

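Normexp on median signals, the counts with both arrays well above background, and some settings for lists and correlations were chosen only after the results were seen. No called gene reported reversed its direction. Which of the higher and lower counts within a line was larger turned with the setting, in HepG2 with quantile normalization (150 higher and 140 lower), normexp and the 3-fold threshold, in Hep3B with median scaling (156 and 160) and the 1.5-fold threshold, and in Huh7 with the filter for all 6 arrays, the authors' values, both arrays well above background and the 1.5-fold threshold. The correlation of the HepG2 and Huh7 responses, near 0 in the fit reported, was negative with normexp. The count of genes changed by DDB stayed at 0 under each setting except normexp, which gave 1 (CYP1A1), and an unadjusted p of 0.05, which gave 1283. Without the cell line term, which is the fit with no replicate block for the pairing by line, the count was 0. Omitting the block changed no call of a gene. The mean differences of the 20 genes named across lines were recomputed 360 times, and 0 had the opposite direction. These genes were chosen for the same direction in all 3 lines, so leaving out a line or array could not reverse a mean. Other variance priors and the fit without the cell line term leave the means unchanged. The count of 0 therefore says little about how the means depend on the processing. Of 1114 recomputed values for the genes reported between lines, 1105 kept their direction and side of the threshold, 4 were no longer past it (JAK3 with the filter for all 6 arrays and with the authors' values), and the opposite direction was seen 5 times for GOT1, whose difference was near 0, and 0 times for the other genes. Apart from GPT and GOT1, these genes were chosen for the largest differences, so these shares do not describe the calls between lines in general. Of the 16 genes the rule took within each line, 13 in HepG2, 8 in Hep3B and 11 in Huh7 were less than 2-fold apart with normexp, 2, 1 and 1 with the mean of probes, and 0 in each line with quantile normalization or median scaling. With an array or line left out, the counts between lines ranged from 7195 to 7455 for HepG2 and Hep3B, from 7961 to 8486 for HepG2 and Huh7, and from 6326 to 6748 for Hep3B and Huh7. Where this left 1 array in an arm, that array was assumed to vary like the others. Signal over background limits the counts, since settings that drop or dampen dim probes lower them by construction, and so do the size thresholds.

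In the order HepG2 against Hep3B, HepG2 against Huh7 and Hep3B against Huh7, the genes past the threshold numbered 4287, 4828 and 3832 with normexp, 4207, 4608 and 3644 with the filter for all 6 arrays, and 4228, 4608 and 3607 with the authors' values. With no minimum size they numbered 13544, 14291 and 12541. On the control arrays alone, the genes at least 2-fold apart numbered 4453, 5088 and 3956 with normexp, 4421, 4874 and 3812 with the filter, and 4427, 4843 and 3779 with the authors' values.

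For DDB against control, the genes at least 2-fold higher and lower numbered 21 and 7 in HepG2, 39 and 24 in Hep3B, and 26 and 39 in Huh7 with normexp. With no filter they numbered 276 and 290, 389 and 347, and 318 and 393. With the filter for all 6 arrays they numbered 41 and 83, 38 and 34, and 48 and 40. The authors' values gave 44 and 68, 39 and 36, and 42 and 40. With both arrays well above background they numbered 72 and 143, 64 and 57, and 88 and 69. At 1.5-fold they numbered 583 and 1080, 471 and 500, and 644 and 575. At 3-fold they numbered 52 and 20, 81 and 60, and 61 and 88.

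The number of lists past the threshold for DDB was 1 in the fit reported. It was 5 with normexp and 0 with quantile normalization, median scaling, the filter for all 6 arrays, an estimated correlation and fry. It ranged from 0 to 3 with a line left out, at 0 without Hep3B and 3 without Huh7. The number was also 1 with no filter, with the authors' values and without HepG2, but the list that passed there was not the NRF2 targets. Their adjusted p from camera was 0.195, 0.0611 and 0.288 in these settings. For the NRF2 targets, the adjusted p from limma's camera was 0.0390 in the fit reported and ranged from 0.0263 (without Huh7) to 0.861 (estimated correlation). For differences between lines, 20 lists passed, and 0 with an estimated correlation.

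The correlation of responses of HepG2 and Hep3B was 0.0848 over genes well above background on all 6 arrays and 0.0736 with the authors' values. For HepG2 and Huh7 it was -0.0259 with normexp, 0.0494 with quantile normalization, 0.0563 over genes well above background on all 6 arrays and 0.0884 with the authors' values. For Hep3B and Huh7 it was 0.161 with normexp, 0.0230 with no filter, 0.150 over genes well above background on all 6 arrays and 0.152 with the authors' values. Apart from the dim probes and the smaller sets of genes, the cause of these shifts was not tested.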

Other observations

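The choice of the genes below that belong to no list was made only after the results were seen. Genes of cholesterol synthesis and uptake, which act together under the sterol-sensing factor SREBP2, were lower with DDB in Hep3B (median -0.09, percentile 0.00 of matched random lists) and Huh7 (median -0.15, percentile 0.01), and were not lower in HepG2 (median 0.17, percentile 74.0). Among them STARD4, a sterol carrier, was at -0.15 in Hep3B, -0.28 in Huh7 and 0.36 in HepG2. Low percentiles were common in these pairs, since in Hep3B secreted hepatocyte proteins (0.00), genes of fatty acid oxidation (0.01), NF-kB inflammatory genes (0.01), oncofetal genes (0.01) and acute phase proteins (0.29) also lay low, as did oncofetal genes (0.41) and acute phase proteins (0.08) in Huh7. These are values from 1 pair of arrays each, the difference between lines was not tested, and none of these list results passed the test across lines.

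TXNIP and ARRDC4, arrestin-like genes that respond to glucose, were lower with DDB in Huh7, at -1.53 and -1.58, while TXNIP was at -0.04 and 0.12 and ARRDC4 at -0.37 and 0.46 in HepG2 and Hep3B. In HepG2, KLF2, a transcription factor, was higher by 1.43 and DUSP5, a phosphatase of the ERK pathway, by 1.32.

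Along the chromosomes, Huh7 had a run of 15 genes around SNRPN on chromosome 15 that were well above background in both other lines and not in Huh7, where shuffles of the gene order gave at most 4. The run holds SNRPN and SNURF, IPW, PWARSN and small nucleolar RNAs that share 1 host transcript, so its members are not independent. SNRPN was at 2.49 and 2.47 in HepG2, 4.77 and 4.71 in Hep3B, and -6.46 and -6.26 in Huh7. Loss of the whole chromosome segment could give this, but UBE3A, the next gene along, was well above background on both Huh7 arrays, with Huh7 minus the other 2 lines at -0.0835, which argues against that loss. This region is imprinted, with the SNRPN transcript made from the paternal copy, and silencing or loss of that copy alone may explain the run but was not tested. HepG2 had a run of 5 (ENPP5, CYP39A1, SLC25A27, TDRD6 and PLA2G7 on chromosome 6).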
